A study of Homo sapiens with 24 samples.

How the data were processed

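Messenger RNA was sequenced from human induced pluripotent stem cells (iPSC) of the established line 201B7 and from presomitic mesoderm (PSM) made from them, the embryonic tissue that divides into somites. Per the labels, PSM was induced in 2 steps of 24 h each. The first medium held 10 µM CHIR99021, a GSK3 inhibitor that activates Wnt signalling, with 50 ng/ml activin A and 20 ng/ml bFGF. The second held 10 µM SB431542, an inhibitor of activin and TGF-beta receptors, with 3 µM CHIR99021, 250 nM LDN193189, which blocks BMP receptors, and 20 ng/ml bFGF. The 24 libraries form 10 groups, which are the parental line (WT) and knockouts (KO) of HES7, DLL3, LFNG and MESP2, each as iPSC and as PSM. WT has 3 experiments and HES7-KO 3 clones per stage, and each other knockout has 2 clones per stage, 9 clones in all. Per the labels the knockouts were made in a line that carries a Hes7-luciferase reporter, which the WT line lacks. A difference between a knockout and WT is therefore confounded with the reporter, the history of the clones and any batch, while the knockouts share the reporter among themselves. The libraries were made with a stranded mRNA kit, per the labels' protocols. The WT experiments and the clones are separate by their labels. The p-values measure the spread between these libraries, in which an experiment and a clone are different kinds of replicate.

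The deposited values are FPKM, fragments per kilobase of transcript and per mapped fragment total, 1 table for the whole series. Per the submitters' processing notes, bcl2fastq 2.17.1.14, cutadapt 1.14, HISAT2 2.1.0, Cufflinks 2.2.1 and Cuffdiff were used with the hg38 genome. The settings, the gene annotation, the use of strand in the counting and the version of Cuffdiff were not given in the sources used here. FPKM adjusts for transcript length and total reads but not for the GC content of transcripts. It holds no read counts, so no count model was run. Cufflinks shares out reads between overlapping genes and near-identical copies by a model, and values of such genes are uncertain.

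The table has 19950 rows, of which 1558 are 0 in all libraries. By Ensembl identifier 19719 were matched to GENCODE release 29 on hg38, and coordinates come from that match. Symbols written as dates, and the old symbol T of TBXT, were restored from the identifiers, 29 in all, and 47 symbols stand for more than 1 row. Absolute depth is unknown. Relative depth was estimated from the most frequent ratio between libraries among values under 0.6 FPKM, in windows of 0.02 on the log2 scale, with PSM HES7-KO clone 8 as the reference. This depth was 1.38, 1.87 and 0.903 in the iPSC WT experiments and 1.98, 0.839 and 3.06 in the PSM WT experiments. PSM DLL3-KO clone 2 had 1.83, and the other knockout libraries lay between 0.963 and 1.21. At most 15.2% of the compared values lay at the most frequent ratio, so these depths are approximate. Low genes are the least precise, and most so in PSM WT experiment 2 and iPSC WT experiment 3. Between 12460 and 13004 genes had FPKM of 1 or more per library. In the 276 pairs of libraries at most 0.81% of values were identical, so no pair of libraries held the same values.

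Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model per group, variance moderated with a mean trend). Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. They are given with the standard error of the limma contrast. A gene was tested when its FPKM reached 1 in at least 2 libraries of the fit, and called at a Benjamini-Hochberg adjusted p under 0.05. PSM against iPSC in WT and the knockout by stage interactions were fitted on all 24 libraries, and comparisons within a stage on its 12 libraries, so that all groups share 1 estimate of spread. Where 1 library of a pair of clones was left out, the remaining clone was assumed to vary like the other groups.

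Gene lists (26) were fixed before the data were examined and tested with limma camera at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison, and again with an estimated correlation. They cover pluripotency, primitive streak and tailbud, posterior PSM, anterior PSM and somite, Notch, Wnt, FGF and MAPK, retinoic acid, HOX genes, neural, neural crest, lateral plate, intermediate mesoderm, endoderm, endothelial and blood, muscle and sclerotome, p53 targets, hypoxia and glycolysis, the unfolded protein response, cell cycle, imprinted genes, naive and trophoblast-like genes, interferon response, histones, extracellular matrix and EMT, and cadherins.

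The rule for the named genes was also fixed then. It takes the 4 targeted genes, up to 4 called members with the largest change from each list, and the largest called increases and decreases among genes with a mean of at least 5 FPKM in the higher group and no overlap between groups. It takes 10 and 10 for the stage comparison and the PSM knockouts against WT, and 3 and 3 elsewhere. Rows without a symbol, XIST and Y-linked genes are not named. The text names part of these genes, with preference for those whose call held without any 1 library. PER1 and KCNK17, the values of ALOXE3 and RARG in PSM DLL3-KO, LFNG-KO and MESP2-KO, the interaction values compared in the closing part and the luciferase difference between the PSM knockouts were named after their values were seen. So was FOXC1 in PSM HES7-KO, which the rule did not take there.

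The alternatives chosen before the data were examined were a pseudocount of 0.1, no filter, median-of-ratios scaling, other sets of libraries in the fit, a replicate block, each library left out, and the estimated correlation for lists. A correction for GC content (medians in 50 bins, smoothing span 0.3) and fits on the compared groups alone for the comparisons within a stage were added after the data were seen. The iPSC and PSM libraries of a clone come from the same line, which the labels give, so line numbers pair the stages. Deviations from the group mean correlated between the stages at 0.362, 0.435 and -0.0842 in the WT experiments and at 0.02 to 0.0841 in the clones.

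The procedure was tested on simulated data with 200 changed genes per comparison, built from each gene's mean over the libraries of the fit and its pooled spread. At a change of 1 on the log2 scale it recovered 91.0% of changed genes among 14072 for PSM against iPSC in WT. Among 13568 genes it recovered 74.6% for PSM HES7-KO and 68.7% for PSM DLL3-KO against WT, and among 14072 it recovered 49.3% for the HES7-KO interaction. At 0.5 the shares were 38.8%, 28.4%, 13.4% and 4.48%, so small changes are mostly missed. Wrong calls averaged 4.89% of calls over 19 comparisons and reached 9.21%. Every group was given the same spread there, although the median SD was 0.20 in PSM WT and 0.092 in PSM MESP2-KO. These shares hold for equal spreads and may differ where the spreads of the groups are unequal. The limit this test had to meet was replaced after its first values were seen, without a change to the data or the fit. A simulated shift of 0.5 in a list of 20 genes was called in 20 of 20 draws, and 1 of 500 unmoved lists was called. These draws varied each gene independently and used lists of random genes. They therefore do not show how often lists of correlated genes are called wrongly at the preset correlation.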

Results

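RNA sequencing was analysed in 24 libraries of human iPSC and of PSM derived from them. Each stage held 3 experiments of the WT line 201B7, 3 HES7-KO clones and 2 clones each of DLL3-KO, LFNG-KO and MESP2-KO. The targeted genes belong to the segmentation clock, the oscillating network that times somite formation, and the comparisons ask what their loss changes in PSM. Values are FPKM, given as mean ± SD, and folds are on the log2(FPKM + 1) scale with their standard errors. Read counts were not used here and only relative depth could be estimated, between 0.839 in PSM WT experiment 2 and 3.06 in PSM WT experiment 3. The median SD between libraries of a group was 0.20 on the log2 scale in PSM WT (n = 3) and 0.18 in iPSC WT (n = 3), and at most 0.14 in the knockout groups. The spread shared by all groups may therefore understate the error of the WT means, and p-values against WT may be too small. Coordinates are those of GENCODE 29 on hg38.

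The transcripts of the targeted genes were examined first. HES7, a transcriptional repressor that oscillates in PSM (chromosome 17, 8120590 to 8124092), stood at 156 ± 29.3 FPKM in PSM WT (n = 3) and at 555 ± 125 in PSM HES7-KO (n = 3). It rose by 1.82 ± 0.17 (limma, adjusted p = 9.8e-05) in the knockout of its own gene. LFNG, a glycosyltransferase that modifies Notch (chromosome 7, 2512529 to 2529177), fell by 1.54 ± 0.21 in PSM LFNG-KO, from 216 ± 59.9 (n = 3) to 71.7 ± 8.63 FPKM (n = 2; adjusted p = 0.0043). This call was lost without LFNG-KO clone 2 (log2 change -1.42, adjusted p = 0.073). DLL3, a Notch ligand (chromosome 19, 39498895 to 39508481), fell by 2.52 ± 0.48 in PSM DLL3-KO, from 411 ± 172 (n = 3) to 85.2 ± 76.0 FPKM (n = 2; adjusted p = 0.026), with 139 FPKM in clone 2 and 31.4 in clone 6. That call was lost without PSM WT experiment 1 (-2.22, adjusted p = 0.065), without DLL3-KO clone 6 (-1.47, adjusted p = 0.24) and in a fit on the compared groups alone (adjusted p = 0.13). MESP2, a transcription factor of the anterior PSM (chromosome 15, 89760591 to 89778754), was near the detection limit, at 1.05 ± 0.319 FPKM in PSM WT (n = 3) and 0.744 ± 0.241 in PSM MESP2-KO (n = 2), a log2 difference of -0.23 ± 0.31 (adjusted p = 0.67). Which part of each gene was altered is not stated in the sources used here, and a gene altered in few bases can keep its transcript, so the levels of HES7 and MESP2 do not check the labels of their knockouts. The reporter transcript, luciferase, was listed at 0 in all iPSC WT libraries and reached at most 0.0269 FPKM in PSM WT. It stood between 8.27 and 9.02 FPKM on average in the 4 iPSC knockout groups. In PSM it reached 1904 ± 464 FPKM in HES7-KO (n = 3), 429 ± 103 in DLL3-KO (n = 2), 794 ± 69.4 in LFNG-KO (n = 2) and 535 ± 9.46 in MESP2-KO (n = 2).

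**Figure D1:**
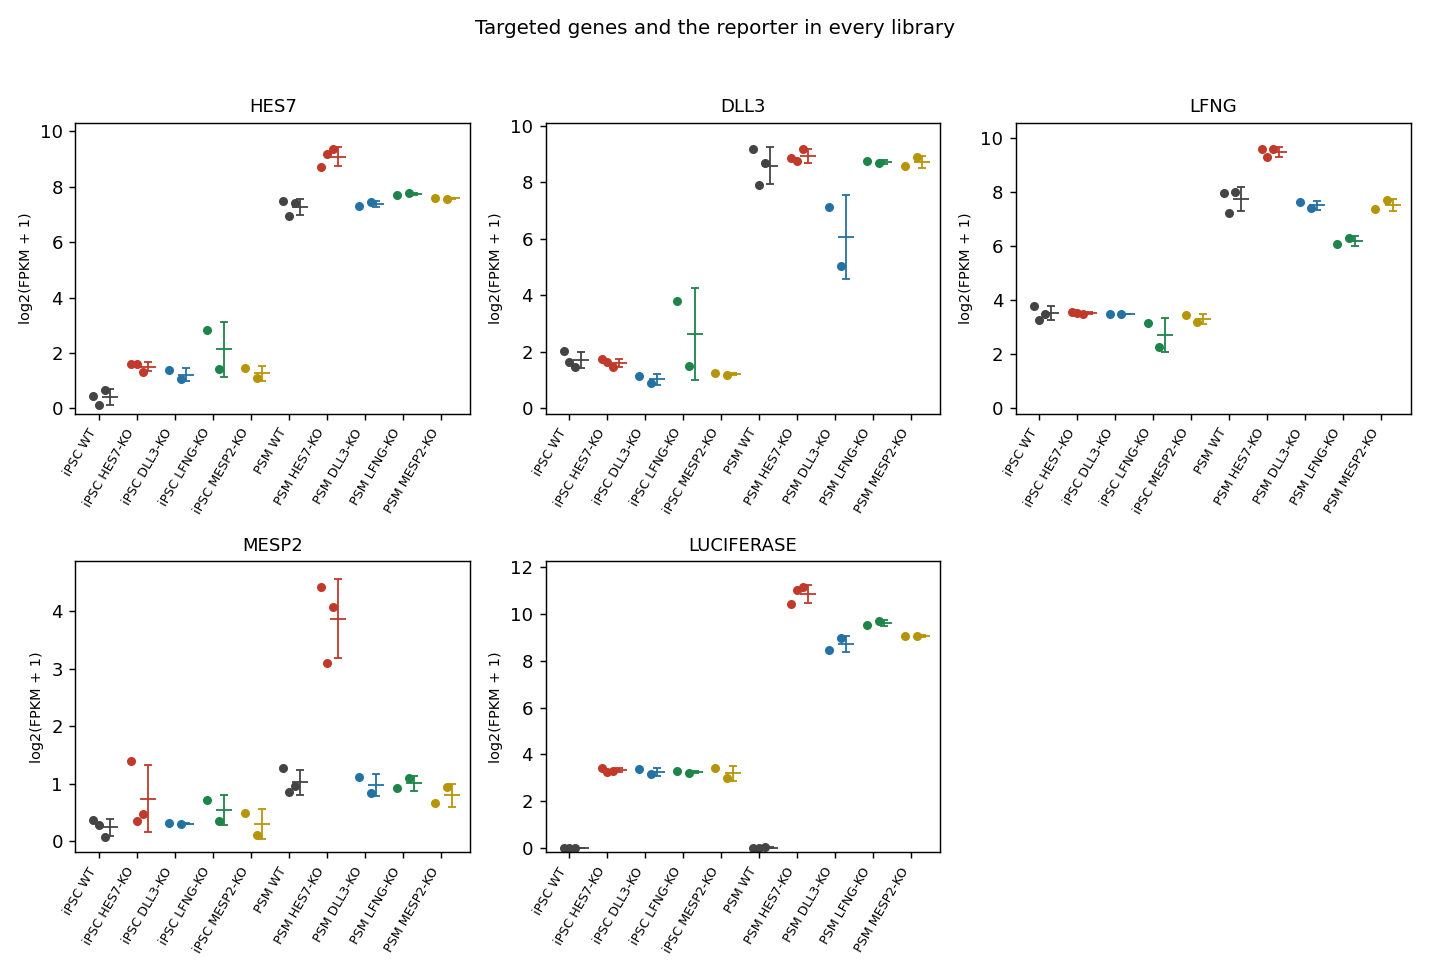
Expression of HES7, DLL3, LFNG, MESP2 and luciferase as log2(FPKM + 1) on the vertical axis in the 10 groups on the horizontal axis, with points for libraries and bars for mean ± SD. HES7, LFNG and MESP2 were highest in PSM HES7-KO, at means of 555, 718 and 14.6 FPKM, and luciferase was near 0 in the WT libraries of both stages.

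The first comparison asks which genes changed when WT iPSC became PSM. Genes of posterior PSM were near 0 in iPSC and among the most abundant in PSM. MSGN1, a transcription factor that directs PSM fate (chromosome 2, 17816496 to 17817101), rose from 0.107 ± 0.0927 to 429 ± 26.2 FPKM (n = 3 each; 8.60 ± 0.53, adjusted p = 7.6e-11), and TBX6, a T-box factor of the same tissue (chromosome 16, 30085793 to 30091887), by 7.31 ± 0.32 from 0.863 ± 0.172 FPKM (adjusted p = 6.2e-13). APLNR, the apelin receptor, rose by 8.74 ± 0.52 to 871 ± 187 FPKM, TBXT, the brachyury factor, by 6.56 ± 0.34, and ALDH1A2, which makes retinoic acid, by 7.12 ± 0.21. The clock genes HES7 (6.87 ± 0.26), DLL3 (6.89 ± 0.47) and LFNG (4.21 ± 0.21) rose as well. MESP2 changed by 0.79 ± 0.28 (adjusted p = 0.023), a call lost without iPSC WT experiment 3 (adjusted p = 0.075) or PSM WT experiment 1 (adjusted p = 0.087). Genes of pluripotency fell, among them TDGF1, a Nodal co-receptor (-6.27 ± 0.45), SOX2 (-4.83 ± 0.29) and NANOG (-4.77 ± 0.18, adjusted p = 7.3e-14), which went from 42.2 ± 1.47 to 0.634 ± 0.521 FPKM. Of 14072 genes tested, 4252 were called higher and 3641 lower in PSM, and 1511 and 1075 of these changed at least 2-fold.

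Of the 26 fixed lists, 11 were called between the stages, and 4 of them held with an estimated correlation. Of 20 pluripotency genes, 18 fell and none rose (camera adjusted p = 5.3e-13, and adjusted p = 0.042 with an estimated correlation). Of 25 genes of extracellular matrix and epithelial-mesenchymal transition, 21 rose and 1 fell (adjusted p = 5.3e-13, and 0.021 with an estimated correlation), including CDH11, a mesenchymal cadherin (6.01 ± 0.20), and SNAI2, a repressor of epithelial genes (5.33 ± 0.15). Of 20 primitive streak and tailbud genes, 16 rose and 3 fell, or 17 and 3 adjusted over the list alone (adjusted p = 5.0e-07, and 0.042 with an estimated correlation), including MIXL1 (6.09 ± 0.24) and CDX1 (6.16 ± 0.31). Of 23 p53 targets, 18 rose and 1 fell (adjusted p = 2.7e-05, and 0.042 with an estimated correlation), including CDKN1A, which halts the cell cycle (2.52 ± 0.17). The other 7 were called upward only at the preset correlation. These were posterior PSM (16 of 17 rose, adjusted p = 4.6e-12, and 0.0502 with an estimated correlation), anterior PSM and somite (10 rose and 2 fell of 12, 4.7e-05 and 0.088), and Wnt targets (19 and 2 of 24, 4.0e-08 and 0.071). HOX genes (15 of 19 rose, or 16 adjusted over the list alone, 2.5e-07 and 0.24), FGF and MAPK targets (15 and 2 of 25, 0.0013 and 0.18), lateral plate (6 and 1 of 9, or 7 and 1 over the list alone, 0.0094 and 0.13) and Notch (16 and 6 of 30, 0.024 and 0.28) were the rest. Unless given, counts adjusted over the list alone were equal.

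The other 15 lists were not called, at adjusted p values of 0.15 for intermediate mesoderm and for cadherins, 0.30 for muscle and sclerotome, and 0.42 for retinoic acid, neural, neural crest, naive and trophoblast-like, and histone genes. The values were 0.43 for hypoxia and glycolysis, 0.48 for the unfolded protein response, 0.51 for endothelial and blood, 0.62 for endoderm, 0.64 for cell cycle, 0.64 for imprinted genes and 0.64 for interferon response. In the retinoic acid list 5 members rose and 6 fell (6 and 6 adjusted over the list alone), with a median of -0.04 and a mean of 1.68. Median and mean also differed in sign for endoderm (-0.64 and 0.28), endothelial and blood (-0.51 and 0.08) and cell cycle (0.07 and -0.03).

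The comparison of PSM HES7-KO with PSM WT asks what the loss of the core oscillator changed. Single genes of the anterior PSM and of Notch signalling rose, while neither list was called (adjusted p = 0.32 and 0.17). Members of the anterior PSM and somite list moved both ways, since ALDH1A2 and FOXC1 of that list were called lower. FOXC1 was called lower in the other 3 knockouts too. MESP2 rose by 2.84 ± 0.28 to 14.6 ± 6.51 FPKM (n = 3; adjusted p = 0.00015), MESP1, a related factor (chromosome 15, 89748661 to 89751310), by 2.51 ± 0.23 to 15.8 ± 2.24 (adjusted p = 0.00010), and RIPPLY2, a repressor that sets the somite boundary, by 1.70 ± 0.27 (adjusted p = 0.0025). LFNG rose by 1.76 ± 0.19 to 718 ± 89.5 FPKM (adjusted p = 0.00026) and HES1, another Notch effector (chromosome 3, 194136145 to 194138732), by 1.96 ± 0.16 to 18.8 ± 3.16 (adjusted p = 5.6e-05). ALOXE3, a lipoxygenase gene next to HES7 (chromosome 17, 8095900 to 8119047), rose from 1.55 ± 0.453 to 35.1 ± 1.19 FPKM (3.84 ± 0.16, adjusted p = 1.5e-07). ALDH1A2 (chromosome 15, 57953424 to 58497866) fell from 229 ± 9.75 to 64.3 ± 5.10 FPKM (-1.82 ± 0.09, adjusted p = 6.5e-07), and TBXT (-1.05 ± 0.18), the protocadherin PCDH19 (-1.56 ± 0.20) and TAC1, the precursor of substance P (-3.79 ± 0.29, adjusted p = 3.3e-05), fell with it. Genes of other lineages moved both ways. FOXA2, of endoderm and axial mesoderm, rose by 2.12 ± 0.16 to 5.33 ± 0.499 FPKM, SOX2 by 2.07 ± 0.37 and PAX2, of intermediate mesoderm, by 1.59 ± 0.18. LMO2, a blood and endothelial cofactor (-2.61 ± 0.29), TBX3 (-1.36 ± 0.19) and ACTC1, cardiac actin (-1.55 ± 0.21), fell. Some genes named here were also called the same way in other knockouts, against the same WT libraries. SOX2 rose by 2.05 in DLL3-KO and 1.54 in LFNG-KO, HES1 by 0.97 in LFNG-KO and FOXA2 by 0.92 in MESP2-KO. TAC1 (-1.67 and -1.95), PCDH19 (-1.03 and -1.37) and LMO2 (-1.33 and -1.68) fell in LFNG-KO and MESP2-KO. ALDH1A2 (-0.45) and ACTC1 (-0.88) fell in MESP2-KO. On the compared groups alone most named calls of these knockouts were lost. ALOXE3, PAX2 and TBX3 were called in the same direction in the other 3 knockouts too, against the same WT libraries. ALOXE3 rose there by 1.13 ± 0.18 in DLL3-KO, 1.77 ± 0.18 in LFNG-KO and 1.49 ± 0.18 in MESP2-KO, to 4.51, 7.63 and 6.19 FPKM. It lost the call without DLL3-KO clone 2 (adjusted p = 0.061) or 6 (0.20), and on the compared groups alone in DLL3-KO (0.096) and MESP2-KO (0.056). PAX2 rose by 0.87 to 1.01 and TBX3 fell by 0.95 to 1.30. These calls were lost without either clone of each knockout (adjusted p = 0.072 to 0.30 for PAX2 and 0.055 to 0.38 for TBX3). Without PSM WT experiment 1 they were lost for PAX2 in DLL3-KO (0.059) and MESP2-KO (0.056) and for TBX3 in DLL3-KO (0.084). On the compared groups alone they were lost except for TBX3 in LFNG-KO (0.062 to 0.15). PAX2 also lost them with the replicate number as a block in DLL3-KO (0.052) and MESP2-KO (0.056), and TBX3 in DLL3-KO at a pseudocount of 0.1 (0.058) and without the filter (0.051).

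In that comparison 1251 of 13568 genes were called higher and 788 lower, 205 and 127 of them by at least 2-fold. Higher calls made up 61.4%, 52.7% after median-of-ratios scaling and 51.8% with the correction for GC content. The count of 2039 fell to 905 without HES7-KO clone 7, to 1038 without clone 8 and to 854 in a fit on the compared groups alone. Of 86 named genes called, 60 kept the call without any 1 library. Among them was every gene named here for this comparison except FOXC1, which is outside the 86. A pair of lists was called. Of 26 hypoxia and glycolysis genes, 9 rose and 1 fell, or 12 and 2 adjusted over the list alone (adjusted p = 0.017, and adjusted p = 0.71 with an estimated correlation), including DDIT4, a stress-induced inhibitor of mTORC1 (1.16 ± 0.21), and ENO2, a glycolytic enzyme (1.03 ± 0.14). Of 12 histone genes, which have near-identical copies, 4 rose and none fell, also over the list alone (adjusted p = 0.030, and 0.71 with an estimated correlation), and that list was not called without the filter (adjusted p = 0.17).

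**Figure D2:**
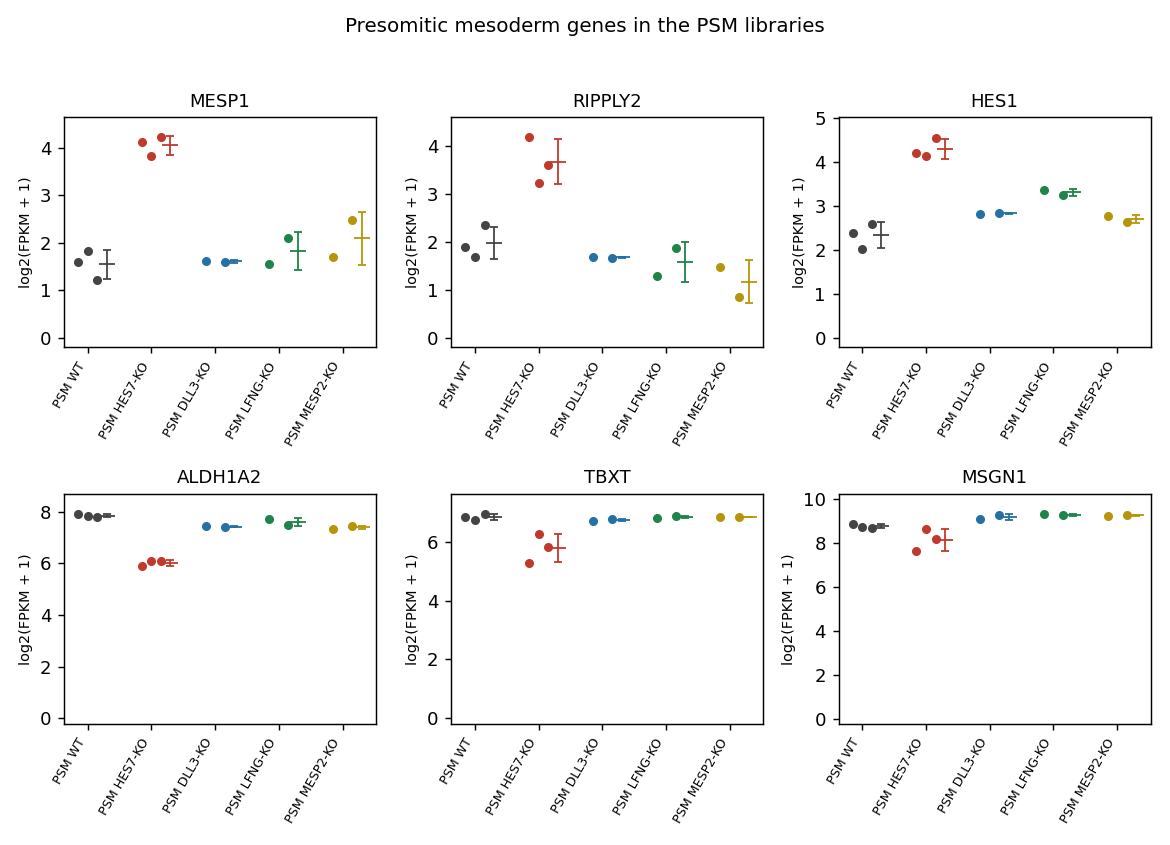
Expression of MESP1, RIPPLY2, HES1, ALDH1A2, TBXT and MSGN1 as log2(FPKM + 1) on the vertical axis in the 5 PSM groups on the horizontal axis, with points for libraries and bars for mean ± SD. In HES7-KO, MESP1, RIPPLY2 and HES1 had means of 15.8, 12.3 and 18.8 FPKM against 1.97, 3.01 and 4.13 in WT, and ALDH1A2 had 64.3 against 229.

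HES7-KO was next compared with the mean of the other 3 PSM knockouts, which carry the same reporter. MESP2 (2.94 ± 0.24, adjusted p = 0.00015), LFNG (2.42 ± 0.17, adjusted p = 2.2e-05), MESP1 (2.22 ± 0.20), RIPPLY2 (2.21 ± 0.24, adjusted p = 0.00059), HES1 (1.35 ± 0.14), FOXA2 (1.52 ± 0.14) and EFNA1, an ephrin (1.25 ± 0.11), were again higher. The mean of the other knockouts includes LFNG-KO, where LFNG is lowered (71.7 ± 8.63 FPKM against 181 ± 20.5 in DLL3-KO and 184 ± 28.9 in MESP2-KO, n = 2 each), which enlarges the difference of LFNG. HES7 itself was higher by 1.53 ± 0.14 (adjusted p = 0.00022), ALOXE3 by 2.38 ± 0.14 (adjusted p = 7.0e-06) and luciferase by 1.72 ± 0.15 (adjusted p = 0.00016). ALDH1A2 was lower (-1.44 ± 0.08, adjusted p = 5.3e-06), at 64.3 ± 5.10 FPKM (n = 3) against 170 ± 3.01 in DLL3-KO, 193 ± 20.4 in LFNG-KO and 167 ± 7.12 in MESP2-KO (n = 2 each), as were TAC1 (-2.15 ± 0.25) and CYTL1, a secreted cytokine-like protein (-1.77 ± 0.23). These calls held without any 1 library, which was not run for luciferase. MSGN1 was lower (-1.09 ± 0.16, adjusted p = 0.0058), but not in the fit on all 24 libraries (adjusted p = 0.35). TBXT was lower (-1.02 ± 0.16, adjusted p = 0.0081), but not without HES7-KO clone 8 (adjusted p = 0.052) nor with all 24 libraries (adjusted p = 0.10). In all 76 genes were called higher and 71 lower, 26 and 18 by at least 2-fold. The count of 147 was 79 without HES7-KO clone 7, 52 without clone 8, 91 without DLL3-KO clone 6, 89 without LFNG-KO clone 12 and 91 without MESP2-KO clone 11. It was 250 with all 24 libraries and 221 on the compared groups alone.

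In the same comparison the Notch list was higher, with 4 of 30 members called and 10 adjusted over the list alone (adjusted p = 1.4e-07, and adjusted p = 0.13 with an estimated correlation). This list holds DLL3 and LFNG, which are targeted in the other knockouts, and HES7. HOX genes were lower, with 2 of 19 called and 7 over the list alone (adjusted p = 1.4e-07, and 0.64 with an estimated correlation). The unfolded protein response list was lower, with 0 of 20 called by limma and 5 adjusted over the list alone (adjusted p = 1.1e-06, and 0.64 with an estimated correlation).

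PSM DLL3-KO differed from PSM WT in few genes that held without any 1 library. CDX4, a caudal-type homeobox gene (chromosome X, 73447254 to 73455245), rose from 2.73 ± 0.538 (n = 3) to 21.1 ± 0.238 FPKM (n = 2; 2.58 ± 0.18, adjusted p = 7.4e-05), and GPR50, an orphan receptor related to the melatonin receptors (chromosome X, 151176653 to 151181465), to 7.40 ± 2.32 (2.35 ± 0.20, adjusted p = 0.00035). ZNF667, a zinc finger gene, fell by 2.75 ± 0.35 (adjusted p = 0.0059), but not on the compared groups alone (adjusted p = 0.061). HES3, a bHLH repressor, rose by 2.00 ± 0.31 (adjusted p = 0.013) and FN1, fibronectin, by 0.94 ± 0.11 (adjusted p = 0.0044). The HES3 call was lost without DLL3-KO clone 2 (adjusted p = 0.056) or clone 6 (adjusted p = 0.20) and on the compared groups alone (adjusted p = 0.055), and that of FN1 without clone 6 (adjusted p = 0.12). HES7 (0.10 ± 0.18), LFNG (-0.22 ± 0.21) and MESP2 (-0.06 ± 0.31) did not pass the test.

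For DLL3-KO 271 genes were called higher and 138 lower, 81 and 27 of them by at least 2-fold. The count of 409 was 200 without PSM WT experiment 1 and 1047 without experiment 3, 42 without DLL3-KO clone 2 and 10 without clone 6. It was 13 on the compared groups alone, 207 with the GC correction, 178 without the filter, 1054 with all 24 libraries and 247 with the replicate number as a block. Higher calls made up 66.3%, 55.4% after median-of-ratios scaling and 55.1% with the GC correction. The lists called upward were pluripotency (1 of 18 called, 3 adjusted over the list alone, adjusted p = 0.035), HOX genes (2 of 19 and 4, adjusted p = 0.028) and hypoxia and glycolysis (0 of 26 higher and 1 lower by limma, 9 and 1 adjusted over the list alone, adjusted p = 0.028). Each had adjusted p = 0.80 with an estimated correlation. The first was lost without the filter (adjusted p = 0.052) and with the block (0.067), the second without the filter (0.44) and the third with the block (0.067). Against the other 3 knockouts limma called 0 genes, with 377 at unadjusted p < 0.05, and DLL3 itself stood at -2.72 ± 0.43 (adjusted p = 0.17). That count was 1 without HES7-KO clone 1, DLL3-KO clone 6 or MESP2-KO clone 7, and 2 without DLL3-KO clone 2. It was 1 with the GC correction or without the filter and 2 with all 24 libraries. The Notch list was lower, with 0 members called by limma and 3 adjusted over the list alone, HOX genes were higher and histone genes lower, with 0 members called either way (adjusted p = 0.033 each, and 0.90, 0.91 and 0.90 with an estimated correlation). All 3 were lost at a pseudocount of 0.1 (adjusted p = 0.066, 0.066 and 0.082) and without the filter (0.056, 0.45 and 0.40). The Notch list holds DLL3 itself, and the mean includes HES7-KO, where the Notch list was called higher and HOX genes lower, so these are not separated from the HES7-KO difference.

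PSM LFNG-KO showed the same direction as DLL3-KO for CDX4 (2.55 ± 0.18, 20.8 ± 2.25 FPKM, n = 2, adjusted p = 4.1e-05) and GPR50 (2.85 ± 0.20, 10.7 ± 2.52 FPKM, adjusted p = 4.1e-05). FN1 rose by 1.36 ± 0.11 to 369 ± 3.01 FPKM (adjusted p = 0.00015). ZNF667 was called lower and was listed at 0 in both clones, against 10.6 ± 2.82 FPKM in WT (n = 3). NPM2, an egg-type histone chaperone (chromosome 8, 22024125 to 22036897), rose by 2.43 ± 0.35 (adjusted p = 0.0055) and CER1, a secreted inhibitor of Nodal and BMP, by 2.77 ± 0.55 (adjusted p = 0.020). NPM2 lost the call without clone 2 (adjusted p = 0.062) or clone 12 (0.060), and CER1 likewise (0.10 and 0.14, and 0.066 on the compared groups alone). HES1 rose by 0.97 ± 0.18 (adjusted p = 0.017), a call also lost without clone 2 (0.14) or clone 12 (0.090) and on the compared groups alone (0.092). HES7 (0.46 ± 0.18, adjusted p = 0.14), DLL3 (0.13 ± 0.48) and MESP2 (-0.02 ± 0.31) did not pass the test. Against the other 3 knockouts LFNG was lower (-1.99 ± 0.19, adjusted p = 0.0031). That mean includes HES7-KO, where LFNG was raised to 718 ± 89.5 FPKM (n = 3), which enlarges the difference. LFNG stood at 71.7 ± 8.63 FPKM in LFNG-KO, 181 ± 20.5 in DLL3-KO and 184 ± 28.9 in MESP2-KO (n = 2 each). NPM2 (2.09 ± 0.31, adjusted p = 0.043) and ALDH1A2 (0.65 ± 0.09, adjusted p = 0.032) were higher than in the mean of the other 3 knockouts. The ALDH1A2 value rests largely on HES7-KO in that mean, at 64.3 ± 5.10 FPKM (n = 3), since LFNG-KO had 193 ± 20.4, DLL3-KO 170 ± 3.01 and MESP2-KO 167 ± 7.12 (n = 2 each), all below the 229 ± 9.75 of WT (n = 3). Both lost the call without any 1 of the 9 knockout libraries, at adjusted p values of 0.053 to 0.61 and of 0.053 to 0.39.

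For LFNG-KO 587 genes were called higher and 242 lower than in WT, 138 and 45 by at least 2-fold. The count of 829 was 508 without PSM WT experiment 1, 1329 without experiment 3, 44 without LFNG-KO clone 2 and 61 without clone 12. It was 69 on the compared groups alone, 528 with the GC correction, 505 without the filter and 1568 with all 24 libraries. Higher calls made up 70.8%, 59.6% after median-of-ratios scaling and 57.6% with the GC correction. The lists called were pluripotency (4 of 18 higher, 5 adjusted over the list alone), HOX genes (2 of 19 and 5) and histone genes (4 of 12 and 4), upward at adjusted p = 0.024 each, and p53 targets, downward (1 of 23 lower, 5 over the list alone, adjusted p = 0.025). All had adjusted p = 0.87 with an estimated correlation. HOX genes were lost without the filter (0.51) and with the GC correction (0.0502), and histone genes without the filter (0.24). Against the other 3 knockouts 6 genes were higher and 2 lower, and 57.1% were higher with the GC correction. That count of 8 was 1 without HES7-KO clone 1, 7 or 8, DLL3-KO clone 2, MESP2-KO clone 7 or MESP2-KO clone 11, 2 without DLL3-KO clone 6 and 3 without LFNG-KO clone 12. It was 5 at a pseudocount of 0.1, 2 without the filter, 1 on the compared groups alone, 15 with all 24 libraries and 2 with the replicate number as a block. The unfolded protein response list was higher with 0 members called by limma, also adjusted over the list alone (adjusted p = 1.0e-05, and 0.79 with an estimated correlation), which is not separated from the lower values of this list in HES7-KO, part of that mean.

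In PSM MESP2-KO, CDX4 (2.50 ± 0.18, adjusted p = 0.00010), GPR50 (2.63 ± 0.20, adjusted p = 0.00010) and FN1 (1.27 ± 0.11, adjusted p = 0.00026) rose and ZNF667 fell (-3.46 ± 0.35, adjusted p = 0.00068). TBC1D15, which regulates the GTPase RAB7, fell by 1.76 ± 0.26 (adjusted p = 0.0071), but not on the compared groups alone (adjusted p = 0.062). LMO2 fell by 1.68 ± 0.33 (adjusted p = 0.018), a call lost without clone 7 or clone 11 (adjusted p = 0.12 each) and on the compared groups alone (adjusted p = 0.063). APELA, a ligand of the apelin receptor, rose by 2.14 ± 0.48 (adjusted p = 0.027), lost without PSM WT experiment 1 (0.062), clone 7 (0.17) or clone 11 (0.15) and on the compared groups alone (0.099). HES7 (0.30 ± 0.18), DLL3 (0.14 ± 0.48) and LFNG (-0.20 ± 0.21) did not pass the test. Against the other 3 knockouts HCCS, which attaches haem to cytochrome c, was the 1 gene called (1.02 ± 0.12, adjusted p = 0.032, with 508 genes at unadjusted p < 0.05). It lost the call without any 1 of the 9 knockout libraries other than LFNG-KO clone 12, at adjusted p up to 0.33 without MESP2-KO clone 11, and with the replicate number as a block (adjusted p = 0.16) or the GC correction (adjusted p = 0.057).

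For MESP2-KO 606 genes were called higher and 293 lower than in WT, 127 and 49 by at least 2-fold. The count of 899 was 518 without PSM WT experiment 1, 20 without MESP2-KO clone 7 and 37 without clone 11. It was 43 on the compared groups alone and 1572 with all 24 libraries. Higher calls made up 67.4%, 52.6% after median-of-ratios scaling and 54.8% with the GC correction. Hypoxia and glycolysis genes were higher (7 of 26 higher and 1 lower, 13 and 2 adjusted over the list alone, adjusted p = 0.0035). Lateral plate genes were lower (2 of 9, 4 over the list alone, adjusted p = 0.034), except at a pseudocount of 0.1 (adjusted p = 0.065). Both had adjusted p = 0.75 with an estimated correlation. Against the other 3 knockouts the single call became 0 without HES7-KO clone 1, 7 or 8, DLL3-KO clone 2 or 6, LFNG-KO clone 2 or MESP2-KO clone 7 or 11, and 2 without LFNG-KO clone 12. The Notch list was lower there, with 0 members called by limma and 1 adjusted over the list alone (adjusted p = 0.0029, and 0.77 with an estimated correlation), which is not separated from its higher values in HES7-KO, part of that mean.

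Differences from WT common to the PSM knockouts were counted next. In the same direction in all 4 knockouts 255 genes were called, 187 higher and 68 lower. They include CDX4, GPR50 and FN1 upward and ZNF667 and CDK10, a cyclin-dependent kinase, downward. CDK10 (chromosome 16, 89680737 to 89696364) overlaps other genes and its value is uncertain. The 4 comparisons share the 3 WT libraries. In 100 simulations of unchanged knockouts against those libraries the highest count was 0, and independent lists would give 0.0483 higher and 0.0031 lower genes. The adjustment leaves few calls in unchanged knockouts, so a simulated count near 0 was largely fixed in advance. Neither value weighs the reporter, the history of the clones, a batch or GC content, which the knockouts may share. Between pairs of knockouts the correlation of folds across genes, which are not independent replicates, was 0.76 to 0.84, and 0.40 to 0.45 in the simulation. For DLL3-KO and LFNG-KO the covariance was 0.12, and 0.020 simulated, and 220 genes were higher and 81 lower in both, where independent lists give 11.7 and 2.46. The 3 WT libraries could not be split into parts of 2 each, so part of the excess may come from the shared controls. The count of 255 was 150 without PSM WT experiment 1 and 598 without experiment 3. Without a knockout clone it was 132 (HES7-KO clone 8), 37 and 9 (DLL3-KO clones 2 and 6), 28 and 42 (LFNG-KO clones 2 and 12), and 16 and 22 (MESP2-KO clones 7 and 11). It was 143 with the GC correction, 131 without the filter, 599 with all 24 libraries and 154 with the replicate number as a block. Higher genes made up 61.7% of them after median-of-ratios scaling and 61.5% with the GC correction.

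For the mean of the 4 PSM knockouts against WT, 1889 genes were called higher and 1125 lower, 136 and 51 by at least 2-fold. The share of FPKM from mitochondrial genes was 7.38 to 9.78% in the PSM WT libraries and 3.69 to 7.74% in the knockouts, with HES7-KO clones 7 and 8 at 4.94 and 3.69%, whereas in iPSC the knockouts lay within the WT range of 4.66 to 6.91%. Higher calls were 62.7%, 50.8% after median-of-ratios scaling and 52.4% with the GC correction. CDX4 (2.54 ± 0.14, adjusted p = 2.6e-06) and GPR50 (2.36 ± 0.15) rose, and ZNF667 (-3.28 ± 0.26), CDK10 (-2.48 ± 0.29) and TAC1 (-2.18 ± 0.24) fell, calls that held under every alternative run. GPR50 was already higher in the mean of the iPSC knockouts, by 1.87 (limma, adjusted p = 4.2e-06), whereas CDX4 stood at 0.009 there (adjusted p = 0.97). In iPSC 964 genes were higher and 579 lower, 56 and 51 by at least 2-fold, and the count of 1543 was 939 without WT experiment 2, 791 without experiment 3, 2335 with the GC correction and 956 with the replicate number as a block. Higher calls in iPSC were 62.5%, 52.96% after median-of-ratios scaling and 51.8% with the GC correction. SCGB3A2, a secretoglobin (chromosome 5, 147870682 to 147882191), rose by 3.63 ± 0.15 (adjusted p = 1.1e-07), and CDK10 (-3.92 ± 0.15) and ZNF667 (-3.33 ± 0.14) fell. Of 12684 genes tested at both stages, 407 were higher and 127 lower in both means, where independent lists give 131.7 and 45.6, and 37 went opposite ways. The 2 stages share no library, but the same lines were used in both. Deviations of the WT experiments correlated between the stages at 0.362, 0.435 and -0.0842, so part of this overlap may come from WT deviations common to both stages. Of the 239 shared PSM genes measured in iPSC, 84 were called the same way and 4 the opposite way in the iPSC mean.

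**Figure D3:**
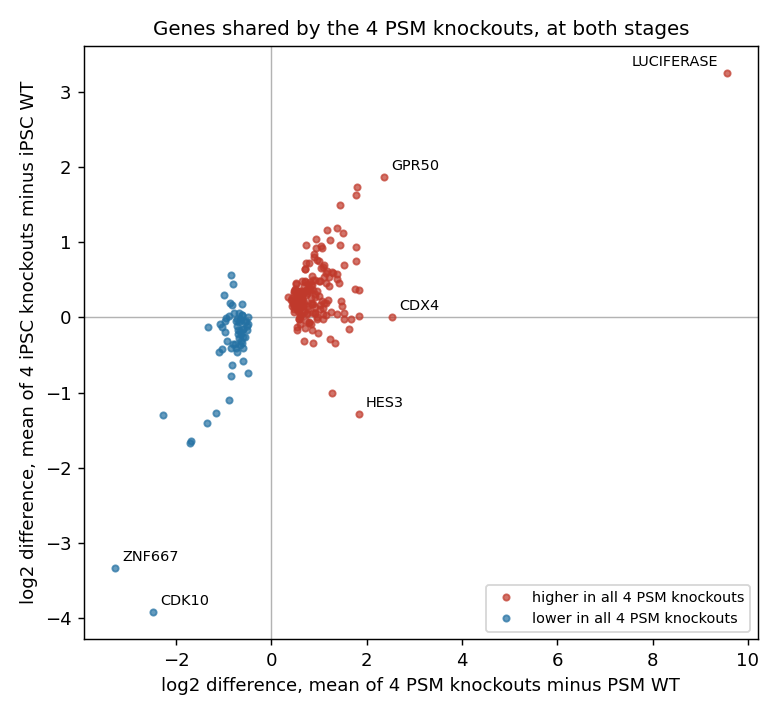
Each point is 1 of the 239 genes called in the same direction in all 4 PSM knockouts and measured in iPSC, with the mean log2 difference of the knockouts from WT in PSM on the horizontal axis and in iPSC on the vertical axis. Red points are higher and blue points lower in PSM, and luciferase lies farthest out, at 9.56 in PSM and 3.26 in iPSC, while CDX4 lies at 2.54 and 0.01.

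In iPSC, before differentiation, every knockout already differed from the same 3 WT libraries in a set of the same named genes. SCGB3A2 rose from 4.41 ± 1.72 FPKM in WT (n = 3) to 74.2 ± 4.86 in HES7-KO (n = 3; 3.85 ± 0.19, adjusted p = 7.4e-07), and by 3.54 ± 0.21 in DLL3-KO, 3.67 ± 0.21 in LFNG-KO and 3.47 ± 0.21 in MESP2-KO (n = 2 each). CDK10, at 42.4 ± 9.29 FPKM in WT, fell in HES7-KO (-4.29 ± 0.19), DLL3-KO (-3.78 ± 0.21), LFNG-KO (-3.66 ± 0.21) and MESP2-KO (-3.96 ± 0.21). HIST1H1C, a linker histone, rose by 2.15 ± 0.15 in HES7-KO, 1.60 ± 0.17 in DLL3-KO, 1.53 ± 0.17 in LFNG-KO and 1.69 ± 0.17 in MESP2-KO. DUSP6, a phosphatase that limits ERK signalling (chromosome 12, 89347232 to 89353271), fell from 186 ± 23.7 FPKM in HES7-KO (-1.31 ± 0.11, adjusted p = 9.2e-05) and to 81.4 ± 8.51 FPKM in LFNG-KO (-1.18 ± 0.13, adjusted p = 0.00069). It also fell in DLL3-KO (-0.82 ± 0.13) and MESP2-KO (-0.92 ± 0.13), calls lost without DLL3-KO clone 2 (adjusted p = 0.11) or on the compared groups alone (adjusted p = 0.089), and without MESP2-KO clone 7 (adjusted p = 0.066). SPRY4, another inhibitor of that pathway, fell by 0.77 ± 0.11 in HES7-KO, and was also called lower in LFNG-KO (-0.69 ± 0.13) and MESP2-KO (-0.54 ± 0.13). SOX15, an HMG-box factor, rose by 2.26 ± 0.16 in LFNG-KO (limma, adjusted p = 2.7e-05). It stood at 7.96 ± 1.04 FPKM in DLL3-KO too (n = 2), against 1.47 ± 0.298 in WT (n = 3).

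Higher and lower calls in iPSC numbered 520 and 380 in HES7-KO, 300 and 131 in DLL3-KO, 208 and 135 in LFNG-KO, and 222 and 145 in MESP2-KO, of 13151 tested. Changes of at least 2-fold were 68 and 68, 55 and 36, 60 and 35, and 44 and 45. For HES7-KO the count of 900 was 432, 384 and 368 without clones 1, 7 and 8, 415 on the compared groups alone and 1591 with the GC correction. Higher calls were 57.8% for HES7-KO, 49.6% after median-of-ratios scaling and 51.9% with the GC correction. For DLL3-KO the count of 431 was 1621, 175 and 182 without WT experiments 1, 2 and 3, 51 and 119 without clones 2 and 6, 31 on the compared groups alone, 843 with the GC correction and 145 with the replicate number as a block. Higher calls were 69.6% there, 55.4% after median-of-ratios scaling and 53.5% with the GC correction. For LFNG-KO the count of 343 was 988, 189 and 179 without WT experiments 1, 2 and 3, 120 and 83 without clones 2 and 12, 40 on the compared groups alone, 833 with the GC correction and 133 with the block. For MESP2-KO the count of 367 was 206 without WT experiment 3, 38 and 65 without clones 7 and 11, 54 on the compared groups alone, 771 with the GC correction and 168 with the block. Higher calls went from 60.6% to 56.5% in LFNG-KO and from 60.5% to 53.9% in MESP2-KO after median-of-ratios scaling.

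In iPSC the same lists were called in several knockouts, in comparisons that share the 3 iPSC WT libraries, so part of this recurrence may come from the shared controls. Histone genes were higher, with 6 of 13 called in HES7-KO (8 adjusted over the list alone, adjusted p = 3.6e-06), 4 in DLL3-KO (6, adjusted p = 0.0028), 4 in LFNG-KO (7, adjusted p = 6.7e-05) and 6 in MESP2-KO (7 higher and 1 lower, adjusted p = 1.9e-06). FGF and MAPK targets were lower, with 5 of 23 called in HES7-KO (8 over the list alone, adjusted p = 0.0040), 1 in DLL3-KO (2, adjusted p = 0.0063), 3 in LFNG-KO (7, adjusted p = 0.0031) and 2 in MESP2-KO (5, adjusted p = 0.0068). Wnt targets were lower with 0 of 14 called by limma in HES7-KO (4 over the list alone, adjusted p = 0.016), DLL3-KO (0, adjusted p = 0.0084) and MESP2-KO (0, adjusted p = 0.0087), but without the filter not in HES7-KO (adjusted p = 0.18) or MESP2-KO (adjusted p = 0.068). Cadherins were higher in HES7-KO, with 2 of 11 called (4 over the list alone, adjusted p = 0.050), but not without the filter (0.18), with the block (0.053) or with the GC correction (0.075). None held with an estimated correlation (adjusted p = 0.52 in HES7-KO, 0.63 in DLL3-KO, 0.72 in LFNG-KO and 0.56 in MESP2-KO).

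A single iPSC library stood apart. In LFNG-KO clone 2, genes of PSM were present at low levels, among them MSGN1 at 16.6 FPKM, where the highest of the other iPSC libraries had 0.303, DKK1 at 12.1 against 0.794 and HES7 at 6.13 against a mean of 1.59 ± 0.359 in the other 8 iPSC knockout libraries. HES7 rose in iPSC LFNG-KO (1.73 ± 0.33, adjusted p = 0.021), but not without this library (adjusted p = 0.093) or WT experiment 2 (0.068) and not on the compared groups alone (0.14). ALDH1A2 rose there by 1.37 ± 0.30 (adjusted p = 0.038), but not without this library (0.14), WT experiment 2 (0.095) or WT experiment 3 (0.090), at a pseudocount of 0.1 (0.062), with the block (0.071) or on the compared groups alone (0.20). In iPSC HES7-KO, HES7 rose from 0.340 ± 0.247 to 1.84 ± 0.295 FPKM (n = 3 each, adjusted p = 0.048), a call lost without each of the 6 libraries compared, at adjusted p values of 0.067 to 0.13. It stood at 1.33 ± 0.369 FPKM in DLL3-KO (adjusted p = 0.20) and 1.42 ± 0.442 in MESP2-KO (adjusted p = 0.19; limma), which did not pass the test. In the mean of the 4 iPSC knockouts HES7 rose by 1.12 ± 0.24 (adjusted p = 0.014), by 0.95 without LFNG-KO clone 2 (adjusted p = 0.0055), and the call was lost without WT experiment 2 (0.98, adjusted p = 0.068).

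Whether a knockout difference changed between the stages was tested as an interaction. In HES7-KO the difference of LFNG from WT was larger in PSM than in iPSC by 1.76 ± 0.30 (adjusted p = 0.0018) and that of ALOXE3 by 3.81 ± 0.19 (adjusted p = 3.2e-10). HES3 differed by 3.44 ± 0.40 with opposite directions, 2.40 ± 0.27 in PSM and -1.04 ± 0.25 in iPSC (adjusted p = 0.030). The iPSC call of HES3 was lost without iPSC WT experiment 1 (adjusted p = 0.056) or 2 (0.068), clone 1 (0.068), 7 (0.094) or 8 (0.091), and on the compared groups alone (0.057). MESP2 differed by 2.34 ± 0.40 (adjusted p = 0.0019), but not at a pseudocount of 0.1 (adjusted p = 0.10). CDX4 differed by 2.59 ± 0.26 in DLL3-KO (adjusted p = 4.9e-05) and by 2.68 ± 0.26 in MESP2-KO (adjusted p = 2.8e-05). The difference of SCGB3A2 was smaller in PSM in HES7-KO (-3.11 ± 0.36). In HES7-KO 719 genes were called, 451 without iPSC WT experiment 1, 413 without iPSC HES7-KO clone 8 and 336 on the compared groups alone. In DLL3-KO 45 were called, and 14 with the line as a replicate block, 29 at a pseudocount of 0.1, 75 with the GC correction and 8 on the compared groups alone. That count was 13 and 21 without iPSC WT experiments 1 and 3, 12 and 16 without iPSC clones 2 and 6, 16, 92 and 81 without PSM WT experiments 1, 2 and 3, and 16 and 8 without PSM clones 2 and 6. In LFNG-KO 107 were called, 48 and 45 without iPSC WT experiments 1 and 3, 28 without iPSC clone 2, 29 and 30 without PSM clones 2 and 12, 67 at a pseudocount of 0.1 and 3 on the compared groups alone. In MESP2-KO 193 were called, 52 without iPSC WT experiment 1, 17 and 35 without iPSC clones 7 and 11, 93 and 307 without PSM WT experiments 1 and 3, 17 and 27 without PSM clones 7 and 11, and 6 on the compared groups alone.

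**Figure D4:**
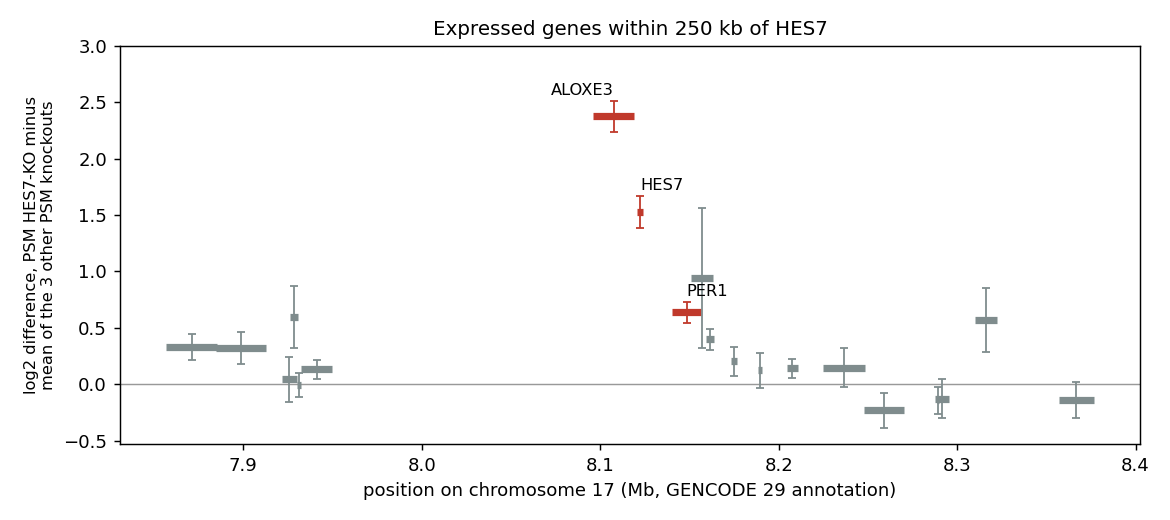
Log2 difference between PSM HES7-KO and the mean of the other 3 PSM knockouts ± SE on the vertical axis against position on chromosome 17 for the expressed genes within 250 kb of HES7, with called genes in red. ALOXE3 (2.38), HES7 (1.53) and PER1 (0.64), a circadian clock gene, were called, and the other genes lay between -0.23 and 0.94.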

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

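The 4 tests on HES7 and ALOXE3 in this part were chosen after the results they address were seen, whereas the interaction tests were planned. The results here are those whose difference between knockout and WT itself differed between iPSC and PSM by the limma interaction test, which called 719 genes for HES7-KO, 45 for DLL3-KO, 107 for LFNG-KO and 193 for MESP2-KO. Values are the knockout difference in PSM minus that in iPSC on the log2(FPKM + 1) scale.

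In HES7-KO the interaction was 1.76 ± 0.30 for LFNG, 2.34 ± 0.40 for MESP2, 3.81 ± 0.19 for ALOXE3, 3.44 ± 0.40 for HES3, -4.05 ± 0.54 for TAC1, -3.11 ± 0.36 for SCGB3A2 and -2.94 ± 0.84 for MAGI2. The HES3 differences behind it were -1.04 in iPSC and 2.40 in PSM. The call of MESP2 was lost at a pseudocount of 0.1 (adjusted p = 0.10, its only loss over the alternatives run). The call of MAGI2 (adjusted p = 0.048) was lost without iPSC WT experiment 1 (0.11), 2 (0.054) or 3 (0.076), iPSC HES7-KO clone 1 (0.11) or 7 (0.12), PSM WT experiment 1 (0.10) or 3 (0.064), and PSM HES7-KO clone 1 (0.059), 7 (0.096) or 8 (0.091). It was also lost at a pseudocount of 0.1 (0.055), on the compared groups alone (0.11), with the line as a replicate block (0.060) and with the GC correction (0.061).

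In DLL3-KO the interaction was 3.15 ± 0.45 for HES3, 2.59 ± 0.26 for CDX4, -2.64 ± 0.41 for SCGB3A2, -1.78 ± 0.28 for SOX15 and -1.54 ± 0.25 for GPAM. SCGB3A2 lost the call without iPSC clone 2 (adjusted p = 0.056) or PSM clone 6 (0.066) and on the compared groups alone (0.16). SOX15 lost it without iPSC clone 2 (0.071) or PSM clone 6 (0.066), at a pseudocount of 0.1 (0.34) and with the line as a replicate block (0.058). GPAM lost it without iPSC clone 6 (0.065) or PSM clone 6 (0.085), on the compared groups alone (0.16) and with that block (0.058).

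In LFNG-KO the interaction was 2.79 ± 0.45 for HES3, 2.79 ± 0.54 for NPM2, -3.37 ± 0.60 for TAC1, -2.77 ± 0.41 for SCGB3A2 and -1.99 ± 0.31 for CDH11. iPSC LFNG-KO clone 2, which holds PSM transcripts, had TAC1 at 19.2 FPKM against 3.44 in clone 12, and CDH11 at 26.1 against 14.8. Without that iPSC library the interaction was -2.28 for TAC1 (adjusted p = 0.048) and -1.60 for CDH11 (adjusted p = 0.044). HES3 lost the call without PSM clone 2 (adjusted p = 0.0503) and TAC1 likewise (0.082). NPM2 lost it without iPSC clone 2 (0.083) or 12 (0.059), without PSM clone 2 (0.089) or 12 (0.079) and at a pseudocount of 0.1 (0.058). On the compared groups alone all 5 were lost, at 0.15 for HES3, 0.081 for NPM2, 0.15 for TAC1, 0.12 for SCGB3A2 and 0.12 for CDH11.

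In MESP2-KO the interaction was 3.10 ± 0.45 for HES3, 2.68 ± 0.26 for CDX4, -2.49 ± 0.60 for TAC1, -2.47 ± 0.41 for SCGB3A2 and -1.96 ± 0.43 for PRSS2. PRSS2 is listed at 0 in all iPSC WT libraries, so its value depends on the pseudocount, and it has a near-identical copy. TAC1 lost the call without iPSC WT experiment 1 (adjusted p = 0.088) or 3 (0.072), iPSC clone 7 (0.17) or 11 (0.11), PSM WT experiment 1 (0.061) or 3 (0.065), and PSM clone 7 (0.16) or 11 (0.13), at a pseudocount of 0.1 (0.055), with the line as a block (0.061) and with the GC correction (0.059). SCGB3A2 lost it without iPSC clone 7 (0.060) and on the compared groups alone (0.093), where HES3 had 0.051. PRSS2 lost it without iPSC WT experiment 1 (0.065), iPSC clone 7 (0.11) or 11 (0.11), PSM WT experiment 1 (0.060), PSM clone 7 (0.14) or 11 (0.084) and on the compared groups alone (0.14).

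The luciferase transcript had the largest interaction named in each knockout, at 7.53 in HES7-KO, 5.46 in DLL3-KO, 6.37 in LFNG-KO and 5.86 in MESP2-KO. It is listed at 0 in iPSC WT, which lacks the reporter, so these values depend on the pseudocount.

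HES7 and its neighbour ALOXE3 were both higher in PSM HES7-KO than in the other knockouts, where ALOXE3 was in turn higher than in WT. A rise of the whole neighbourhood is argued against, since the median difference of the other 18 expressed genes within 250 kb was 0.144, with PER1 (0.64, adjusted p = 0.0068) the only one called. Transcription running on from HES7 into ALOXE3 at a fixed ratio is argued against as the whole cause of the ALOXE3 difference from WT. The ALOXE3 to HES7 ratio was 6.765 times that of WT (0.0509 to 0.0864 against 0.0086 to 0.012). Its median was 0.0311 in the other knockouts and 0.008991 in WT, so part of that factor is not particular to HES7-KO. Whether run-on keeps a fixed ratio to HES7 transcript was not tested. Run-on stays open against the other knockouts, at 1.96 times their ratio and 2.251 times that of all other PSM libraries. HES7 sequence carried in the reporter transcript could give 51.77% of the HES7 difference by the iPSC ratio of HES7 to luciferase (33.8 to 71.9% over libraries), and an earlier form of this test was replaced after its value was seen. That share takes the iPSC ratio (0.1435) to hold in PSM. In PSM DLL3-KO, LFNG-KO and MESP2-KO, HES7 stood at 165 ± 12.0, 213 ± 4.95 and 190 ± 2.925 FPKM (n = 2 each). It was 156 ± 29.3 in WT (n = 3), while luciferase was 429, 794 and 535 FPKM in those knockouts. HES7 exceeded WT there by less than that ratio gives, so the share may be smaller unless HES7 from its own gene was lower there. Luciferase itself stood at 1904 ± 464 FPKM in PSM HES7-KO (n = 3), above the other knockouts with the same reporter. HES7 sequence in the reporter transcript would not account for that rise of luciferase. A loss of repression of HES7 by its own product, which the knockout would bring, was not tested and also stays open.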

How the results depend on the processing

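The GC correction and, for comparisons within a stage, the fits on the compared groups alone were chosen after the data were seen, and all other alternatives were planned. Over the alternatives no value changed direction past its threshold. Of the counts of called genes, 157 stayed within 1.5 times their value and 139 did not. Of the called gene lists, 194 values kept their side of the threshold and 58 did not. For the named genes these numbers were 5150 and 1349, and for the targeted genes 945 and 17, with 8 more past the threshold only in an alternative. For PSM against iPSC in WT, 94 of 95 named genes kept the call under every alternative run, and for PSM HES7-KO against WT 58 of 86, for DLL3-KO 3 of 43, for LFNG-KO 7 of 66 and for MESP2-KO 5 of 64. In the groups of 2 clones a left-out clone leaves a single library, so these calls rest on the spread of the other groups. Except where the construction shows it, as with fewer libraries in a fit or fewer genes tested, the cause was not tested.

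With a library left out in turn, the genes called against PSM WT were 905 to 2156 in HES7-KO, 10 to 1047 in DLL3-KO, 44 to 1329 in LFNG-KO and 20 to 1325 in MESP2-KO. Against iPSC WT they were 368 to 1245, 51 to 1621, 83 to 988 and 38 to 525. Against the other 3 PSM knockouts they were 52 to 120, 0 to 2, 1 to 6 and 0 to 2, where the counts of 0 are from limma with 377 genes for DLL3-KO and 508 for MESP2-KO at unadjusted p < 0.05 with all libraries. For the interactions they were 413 to 833, 8 to 92, 28 to 153 and 17 to 307. The mean of the iPSC knockouts gave 791 to 2111 and the genes shared by all 4 PSM knockouts were 9 to 598. The change of DLL3 in PSM DLL3-KO ranged from -3.58 to -1.47, and that of LFNG in PSM LFNG-KO from -1.80 to -1.40.

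With only the compared groups in the fit, the calls against PSM WT were 854 in HES7-KO, 13 in DLL3-KO, 69 in LFNG-KO and 43 in MESP2-KO, and against iPSC WT 415, 31, 40 and 54. Against the other knockouts HES7-KO had 221 and LFNG-KO 1, and the interactions had 336, 8, 3 and 6. DLL3 in PSM DLL3-KO stayed at -2.52 but was no longer called (adjusted p = 0.13, and 0.065 to 0.24 in the other alternatives that ended this call). These fits have fewer libraries to estimate the spread. Against WT they also leave out knockout groups, whose median SD was at most 0.14, against 0.20 in PSM WT and 0.18 in iPSC WT. How much of the fall in calls came from each was not tested.

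With the GC correction the calls were 207 in PSM DLL3-KO, 528 in PSM LFNG-KO, 1591, 843, 833 and 771 in the iPSC knockouts of HES7, DLL3, LFNG and MESP2, 1 for DLL3-KO and 0 for MESP2-KO against the other knockouts, 75 for the DLL3-KO interaction, 2335 for the mean of the iPSC knockouts and 143 for the shared genes. With all 24 libraries in the fit they were 1054 in PSM DLL3-KO, 1568 in LFNG-KO, 1572 in MESP2-KO, 250, 2 and 15 for HES7-KO, DLL3-KO and LFNG-KO against the other knockouts, and 599 for the shared genes. Without the filter they were 178 in PSM DLL3-KO, 505 in PSM LFNG-KO, 1, 2 and 0 for DLL3-KO, LFNG-KO and MESP2-KO against the other knockouts and 131 for the shared genes. At a pseudocount of 0.1 they were 5 for LFNG-KO against the other knockouts, 29 for the DLL3-KO interaction and 67 for the LFNG-KO interaction.

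The line as a replicate block, in the interactions, moved the DLL3-KO count to 14 and no other count of genes by over 1.5 times. Within a stage the numbers do not pair the libraries, since deviations of libraries with the same number correlated at -0.155 to 0.177 in PSM and -0.352 to 0.121 in iPSC over 21 pairs each. With the replicate block by number the calls were 247 in PSM DLL3-KO, 145, 133 and 168 in iPSC DLL3-KO, LFNG-KO and MESP2-KO, 2 for LFNG-KO and 0 for MESP2-KO against the other knockouts, 956 for the mean of the iPSC knockouts and 154 for the shared genes. Lists called with this block were 1 in PSM DLL3-KO, 4 in PSM MESP2-KO, 2 for LFNG-KO and 2 for MESP2-KO against the other knockouts.

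With an estimated correlation 4 lists were called between the stages and 0 by camera in each of the 12 knockout comparisons. With the GC correction the lists called were 6 in PSM DLL3-KO and 4 in PSM MESP2-KO, and after median-of-ratios scaling 6 in PSM MESP2-KO. Without the filter they were 1 in PSM HES7-KO, 1 in DLL3-KO, 2 in LFNG-KO, 0 for DLL3-KO against the other knockouts, 2 in iPSC HES7-KO and 5 in iPSC LFNG-KO. At a pseudocount of 0.1 they were 1 in PSM MESP2-KO and 0 for DLL3-KO against the other knockouts.

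Among other splits of the same libraries, 1 of 84 for HES7-KO against the other PSM knockouts gave as many genes, the real one (147, highest other 3), and so did 1 of 100 for the mean of the PSM knockouts (3014, highest other 13) and 1 of 100 for the mean of the iPSC knockouts (1543, highest other 21), a share under 0.05. The other splits mix the groups compared, so a difference between these groups adds to their spread and lowers their counts. With 10 splits a share under 0.05 cannot be reached, for PSM against iPSC in WT (7893, highest other 1415), PSM HES7-KO against WT (2039 and 0), iPSC HES7-KO against WT (900 and 0) and the HES7-KO interaction (719 and 0). Read counts are unknown here, so the counting error of low genes such as MESP2, at 1.05 FPKM in PSM WT, could not be given.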

Other observations

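In this part the median ratio of folds after the GC correction, the share of shared genes with the same sign in iPSC, and all tests on iPSC LFNG-KO clone 2 were chosen after the results were seen. Some further genes changed in PSM HES7-KO against WT, each keeping its call without any 1 library. NR2F1, a nuclear receptor, rose from 0.349 ± 0.258 to 8.42 ± 1.93 FPKM (n = 3 each; 2.80 ± 0.29, adjusted p = 0.00022), RARG, a retinoic acid receptor, by 1.19 ± 0.13, and FN1, fibronectin, by 1.60 ± 0.10. RARG and FN1 were called upward in the other 3 knockouts too, RARG by 0.96 to 0.98, a call lost without DLL3-KO clone 6 (adjusted p = 0.20), LFNG-KO clone 2 (0.10) or MESP2-KO clone 7 (0.12) or 11 (0.054). FN1 lost it without DLL3-KO clone 6 (0.12), and RARG on the compared groups alone in DLL3-KO (0.068) and MESP2-KO (0.056). MEST, an imprinted gene, fell by 1.11 ± 0.16 from 1853 ± 472 to 835 ± 12.4 FPKM, and CXCR4, a chemokine receptor, by 1.04 ± 0.13. DNAJB9, a chaperone of the endoplasmic reticulum, fell by 1.18 ± 0.18. In iPSC LFNG-KO CRABP2, which carries retinoic acid, rose from 50.3 ± 6.06 (n = 3) to 111 ± 8.10 FPKM (n = 2, adjusted p = 0.00030) and MMP17, a membrane metalloproteinase, fell by 1.69 ± 0.20. In iPSC HES7-KO CRABP2 rose by 0.68 ± 0.10 and BMP4 by 0.95 ± 0.18. Against the same WT libraries both were also called higher in iPSC DLL3-KO (0.69 ± 0.11 and 1.18 ± 0.20) and MESP2-KO (0.49 ± 0.11 and 1.01 ± 0.20). BMP4 was called higher in iPSC LFNG-KO too (1.25 ± 0.20), so neither change is particular to HES7-KO.

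The 255 genes called in the same direction in all 4 PSM knockouts were set against GC content, depth and a difference between the lines that was there before differentiation. GC content as the whole cause is argued against, since the median ratio of folds after and before the GC correction was 0.8098 (quartiles 0.73 and 0.91), but it may account for part, because only 40% of the genes kept the call in all 4 knockouts after the correction, where the median fold fell from 0.81 to 0.66 while its standard error went from 0.11 to 0.10, and all 255 kept the call in the mean of the 4. Depth stays open, since its test rests on the shallowest WT library alone, PSM WT experiment 2, at a median position of 0.1364 (quartiles -0.24 and 0.48) between the other WT libraries at 0 and the knockouts at 1, over 249 genes called in all 4 knockouts without it. A difference present before differentiation could account for the direction, with the same sign in iPSC in 85.36% of the 239 genes measured there against 61.1% of the other 12445, while its part in the size is not settled by the median ratio of the iPSC to the PSM difference (0.362), because the genes were chosen for their PSM difference. The reporter, the history of the clones, a batch and GC content at both stages would all give this, and the design confounds them. Deviations of the WT experiments common to both stages could add to the share with the same sign.

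PSM genes were present in iPSC LFNG-KO clone 2, at a median of 2.93% of their level in PSM WT over 30 genes, where the highest median in any other iPSC library was 0.0526%. RNA from PSM cells of the same clone is argued against, since luciferase stood at 8.69 FPKM against 8.63 ± 0.991 in the other 8 iPSC knockout libraries, 0.2378% of the addition that this share would bring. The same value argues against a clone that had begun to differentiate, if the reporter ran with HES7 as in PSM, because HES7 showed 4.54 of the 6.77 FPKM expected (an earlier form of this test was replaced after its value was seen). RNA from PSM WT cells may still be the source, with a largest ratio of 1.257 between the median share and its quartiles, although PCDH19 and KCNK17 lay under 33% of the median share. That outcome depends on the selection of genes, because 3 were tried after the result was seen, and 38 genes with 3 such low ones would argue against it while 11 genes had none.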
